A study of Mus musculus and Homo sapiens with 5 samples.

How the data were processed

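Polyadenylated RNA was sequenced from mouse T cells in 3 groups (fresh medium, Hepa1-6 supernatant, supernatant with lysine) and from human Huh-7 cells in 2 groups (control and SLC3A2 knockdown lentivirus), with 1 GEO sample and 3 library columns per group. Strand was not stated, and the genome build was not given in the sources used here.

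Per the submitters' processing notes, cutadapt 1.9.1, HISAT2 2.0.1, HTSeq 0.6.1 and DESeq2 (no version) were used. Per the file headers, the deposited tables hold raw read counts per gene and library. The deposited FPKM values are those of the authors, per the file headers. In Huh-7 cells they imply 0.952 to 1.07 times the summed counts per library, in proportion to the authors' size factors, and are not used here. In T cells they imply totals that are not proportional to the size factors (highest over lowest ratio 1.05 and 1.01) and that differ by at most 0.00510% between the tables for the supernatant libraries. The log2 fold changes and, for T cells, their standard errors were computed by the authors, per the file headers. Per the file headers, each p-value and adjusted p-value is that of the authors. The signal values (mean normalised counts per comparison or group) are the authors' means of counts divided by size factors, per the file headers. Gene lengths and numbers of genes per KEGG pathway were used as deposited by the authors. For Huh-7 cells the deposited table holds all 58735 annotated genes, 34576 with at least 1 count. The T cell tables hold only genes with an adjusted p under 0.05 and an absolute log2 fold change of at least 1 (2689 and 372 genes). The smallest p and its adjusted value in the first of these imply about 24046 genes tested, and about 7873 past the adjusted threshold at any fold change. In the second, where the smallest p are printed as 0, ranks 3 to 12 imply about 16638 and 4615.

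The design, fixed before the data were examined, called for edgeR over all T cell libraries. This was not possible, since the tables hold selected genes only. Fold changes, standard errors and adjusted p of T cell genes are therefore those of the authors' deposited tables. Means and SD of FPKM and CPM were computed here. Library totals of T cells were recovered from reads, FPKM and gene length of the listed genes, and the authors' size factors from reads and the deposited means. All library totals and CPM of T cells rest on this, and summed counts to check them against are not available. The listed genes held 4.09% to 4.20% of reads in the first table and 0.373% to 0.743% in the second. For genes with 0 reads in a group, folds are lower bounds with a floor of 3 reads over the group, and with 1 to 3 reads a ratio is given with its 95% exact binomial interval. Listed genes whose groups' libraries did not overlap numbered 2649 and 367 by CPM. With 3 libraries against 3, chance gives 10% of unselected genes. The listed genes were selected by p and fold change, so that share is no comparison for them. Alternatives for the tables used edgeR on the listed genes. Its p was adjusted over 24046 genes for both tables, with genes not listed entered as if they had not changed. Counts of called genes also needed an absolute log2 fold change of at least 1. Supernatant with lysine was compared with fresh medium for the 177 genes in both tables, in an edgeR quasi-likelihood fit of the 9 T cell libraries with library totals as the only scaling. In that fit p was adjusted over these 177 genes alone. The covariance of the log2 ratios of these genes was computed beside that of simulated counts but is not given as a test, since the genes were selected by their size in both tables.

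Huh-7 counts were fitted with edgeR 4.0.16 (filterByExpr, TMM, robust quasi-likelihood F-test, Benjamini-Hochberg, adjusted p under 0.05), which left 16870 genes. The biological coefficient of variation was 0.0544. CPM of Huh-7 cells are on library totals multiplied by the TMM factors. Log2 fold changes rest on TMM scaling too.

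Gene lists were fixed before the files were seen. In Huh-7 cells they were ATF4 and amino acid response, aminoacyl-tRNA synthetase, amino acid transporter, lysine metabolism, glycolysis, hypoxia, oxidative phosphorylation, cholesterol synthesis, fatty acid synthesis, cell cycle, hepatocyte, NRF2 and ferroptosis, unfolded protein response, p53, interferon response, antigen presentation, checkpoint ligand and chemokine, epithelial and integrin, ribosomal protein, leukocyte, and fibroblast and endothelial genes. They were tested with limma's camera (3.58.1, inter-gene correlation 0.01, Benjamini-Hochberg over 21 lists), with camera with an estimated correlation and with fry, and set beside 10000 random lists matched on expression and length. In T cells effector, activation, inhibitory receptor, naive and memory, helper and regulatory, IL-2 and STAT, T cell identity, B cell, myeloid, dendritic, natural killer, erythroid and platelet, and hepatoma lists took the place of the hepatocyte, antigen presentation, checkpoint, epithelial, leukocyte and fibroblast lists. There the direction of listed members was compared with that of the other listed genes by Fisher's exact test. It counts members as independent, so its p can be too small where members of a list move together. That test came after the tables were seen to hold selected genes only.

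Genes were named by a rule fixed with the design: the knockdown target; the 10 largest rises and falls per comparison among genes past the threshold with at least 10 CPM in the higher group and no overlap between libraries (predicted genes, ribosomal pseudogenes and receptor segments excepted); up to 4 members per list with the largest change among those past the threshold; and 14 gene names fixed in advance. Other members and the 3 ribosomal RNA genes were named after their values were seen. Of the listed genes 2602 and 367 were found in the GENCODE M21 annotation, used for gene classes only. Among Huh-7 genes 27 symbols are dates, and no such gene is named. Some genes that the rule names are not reported.

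Alternatives were other scalings, filters, fold thresholds and pseudocounts, a replicate block, DESeq2 1.42.0, the authors' own calls and each library left out in turn. On simulated counts with the same means, the Huh-7 fit on 16565 genes recovered 64.2%, 83.6% and 100% of genes changed by a log2 of 0.5, 1 and 2, and called 0.0794% of unchanged genes. The edgeR fit of the first T cell table (2689 genes) recovered 40% at 1 and 71% at 2 and called 0.281% of unchanged genes. For the second table (372 genes) these were 86.0%, 98.9% and 0.538%. Both T cell simulations adjusted p over the listed genes alone and set no fold threshold. Their rates are therefore not those of the alternatives for the tables, which are stricter. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.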

Results

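RNA was sequenced from 5 samples, 1 for each of 5 groups. T cells from mouse spleen were activated with beads carrying antibodies to CD3 and CD28 and grown with 50 U/ml IL-2, the cytokine that drives T cell expansion. For 72 h they were kept in fresh medium, in supernatant from Hepa1-6 cells (a mouse hepatoma line), or in that supernatant with lysine added. Huh-7 cells, a human hepatocellular carcinoma line, carried a control lentivirus or an SLC3A2 knockdown lentivirus. SLC3A2 is the heavy chain that brings amino acid transporters such as SLC7A5 and SLC7A11 to the plasma membrane, and the study concerned uptake of lysine by liver cancer cells and its bearing on T cells.

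Each group had 3 library columns that belonged to 1 GEO sample. The labels do not say whether these were separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical. By the totals recovered from FPKM, reads and gene length of the listed genes, the T cell libraries held about 16946166, 13220895 and 13435684 reads in fresh medium, 17704793, 16993256 and 14185060 in supernatant and 14440530, 15417823 and 18150116 in supernatant with lysine. Those of Huh-7 cells held 23369161, 21058452 and 23279806 counts with the control virus and 23053156, 19945365 and 21967238 with the knockdown virus. All T cell samples carried 1 batch label and both Huh-7 samples another. A label per GEO sample does not show how its library columns were prepared. A difference in culture or preparation between groups is therefore not excluded. The T cell tables list only genes that the authors selected, with an adjusted p under 0.05 and an absolute log2 fold change of at least 1. A gene that was not listed may have changed by less, not passed or not been tested.

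The first comparison asked what hepatoma supernatant did to activated T cells. Genes of the amino acid stress response were higher in supernatant, and some cell cycle genes, mainly of mitosis, were lower. In the authors' deposited table, 14 of 33 ATF4 and amino acid response genes were listed higher and 0 lower, while 15 of 28 cell cycle genes were listed lower and 0 higher. Transcripts made in liver cells, among them Alb (albumin), appeared in the supernatant libraries, and Mpo (myeloperoxidase, of neutrophils) and Mcpt8 (of basophils) were among the largest falls. In all, the authors' deposited table listed 2689 genes, 793 higher and 1896 lower in supernatant. Without supernatant library 2, 1174 genes were lower (edgeR on the listed genes).

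Among genes that respond to amino acid shortage through the transcription factor ATF4, Nupr1 rose by 2.83 ± 0.27 (log2 fold change ± SE) in the authors' deposited table (adjusted p = 1.01e-24). The cationic amino acid transporter Slc7a3 rose by 2.33, the pseudokinase Trib3 by 1.94 and the cystathionine gamma-lyase Cth by 1.89 in the authors' deposited table. Measured here, Trib3 went from 12.3 ± 3.17 FPKM (SD, n = 3) in fresh medium to 45.4 ± 1.34 FPKM (SD, n = 3) in supernatant, and Nupr1 reached 3.46 ± 0.278 FPKM (SD, n = 3) in supernatant. Slc7a5, the leucine transporter that pairs with Slc3a2, rose by 1.09 in the authors' deposited table, and Slc3a2, Slc7a1 and Asns were not listed there. The list stood apart from the other listed genes in direction, with an adjusted p of 8.74e-07 by Fisher's exact test (two-sided, Benjamini-Hochberg over 25 lists with a listed member). The test allows for no correlation between members, so this p and those of the other T cell lists can be too small. Of 25 amino acid transporter genes, Slc7a3, Slc7a5 and Slc1a4 were listed higher (1.08 for Slc1a4) and Slc7a8 lower (-3.91) in the authors' deposited table (exact test, adjusted p = 0.181). Of 20 aminoacyl-tRNA synthetase genes 1 was listed, Eprs, higher by 1.03, and of 17 lysine metabolism genes 1 was listed, Hykk, at -1.61 in the authors' deposited table.

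Ccnb2, a mitotic cyclin, fell by 2.37 ± 0.16, the kinetochore gene Cenpf by 2.08 ± 0.14, the survivin gene Birc5 by 1.75 ± 0.12 and the mitotic kinase gene Plk1 by 1.63 ± 0.20 (log2, SE) in the authors' deposited table. Ccnb2 was at 14.5 ± 0.428 FPKM in fresh medium and 2.73 ± 0.292 FPKM in supernatant (SD, n = 3 each). Mki67, the proliferation marker Ki-67, fell by 1.28 and Top2a by 1.15 in the authors' deposited table. The other 13 cell cycle genes were not listed there, among them the replication genes Mcm2, Mcm3, Mcm4, Mcm5, Mcm6, Mcm7 and Pcna. The direction of the list differed from that of the other listed genes at an adjusted p of 0.0296 (exact test), and with reads scaled by library totals at 0.0616, with the same 15 members lower.

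Activation genes were listed higher. Of 17 activation genes 5, Myc (1.44), Cd69 (1.28), Batf (1.26), Irf4 (1.21) and Egr1 (1.18), rose and 0 fell in the authors' deposited table (exact test, adjusted p = 0.0185). In the inhibitory receptor and exhaustion list Cd200, Lag3, Btla and Tox2 rose by 1.63, 1.36, 1.02 and 1.52 in the authors' deposited table (4 of 16 higher, 0 lower, exact test, adjusted p = 0.0296). With reads scaled by library totals 3 of them were higher (exact test, adjusted p = 0.0640). In the effector list 4 of 21 genes were higher, Lta (1.72), Gzma (1.63), Tbx21 (1.18) and Tnf (1.05), and the chemokine gene Ccl3 was lower at -1.37 in the authors' deposited table (exact test, adjusted p = 0.0801). Ifng, Gzmb, Prf1, Pdcd1 and Stat3 were not listed. Helper and regulatory T cell genes went both ways, 4 higher and 4 lower of 18 (exact test, adjusted p = 0.434). The follicular helper cytokine gene Il21 rose by 2.14, Il5 by 1.34, Il22 by 1.14 and Cxcr5 by 1.03, whereas Il10 fell by 1.99, Il13 by 1.49, Il17f by 1.27 and Il4 by 1.00 in the authors' deposited table. Socs3, a feedback inhibitor of cytokine signalling, was the 1 listed gene of 22 in the IL-2 and STAT list, at 1.07 in the authors' deposited table, and Cd5 the 1 of 15 T cell identity genes, at 1.02. None of 16 naive and memory genes was listed.

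Metabolic lists moved in part. Glycolysis genes were listed higher in 4 of 22 cases and lower in 0 (exact test, adjusted p = 0.0296), led in the authors' deposited table by the hexokinase gene Hk2 (1.91), with Eno2 (1.18), Tpi1 (1.10) and the lactate carrier gene Slc16a1 (1.09). Hypoxia genes were 3 higher and 1 lower of 19 (exact test, adjusted p = 0.181), with Egln3 at 2.11, P4ha2 at 1.78, Vegfa at 1.68 and Anxa1 at -2.08 in the authors' deposited table. Of 16 NRF2 genes, which defend against oxidative stress, Nqo1 fell by 3.05, Hmox1 by 1.96, Srxn1 by 1.20 and Gclc by 1.03, and Osgin1 rose by 1.72 in the authors' deposited table (exact test, adjusted p = 1). Interferon response genes were lower in 4 of 26 cases and higher in 0 (exact test, adjusted p = 0.454), Cxcl10 at -1.72, Oasl2 at -1.30, Mx1 at -1.09 and Rtp4 at -1.04 in the authors' deposited table. Of 26 ribosomal protein genes 3 were listed higher and 0 lower (exact test, adjusted p = 0.0801), among them Rpl13 (1.23) and Rps19 (1.03) in the authors' deposited table. By edgeR on the listed genes Rps19 did not pass (adjusted p = 0.203). Of 12 fatty acid synthesis genes Scd1 rose by 2.45 while Me1 and Fads2 fell by 2.99 and 2.24 in the authors' deposited table. Cycs at -1.02 was the 1 listed of 30 oxidative phosphorylation genes and Eda2r at -2.33 the 1 listed of 17 p53 genes in the authors' deposited table, and none of 22 cholesterol synthesis or 16 unfolded protein response genes was listed.

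The genes with the largest rises and falls were partly of other cell types. Stra6, a retinol transporter gene, rose by 6.81 ± 0.43 (log2, SE) in the authors' deposited table. It went from 0.285 ± 0.148 to 29.9 ± 0.329 CPM (SD, n = 3 each). Hic1, a repressor gene, went from 1.20 ± 0.294 to 16.2 ± 1.96 FPKM (SD, n = 3 each). The other large rises were Alb (6.07), Angptl6 (3.23), Batf3 (2.79), the mitochondrial folate enzyme gene Aldh1l2 (2.77), Ajuba (2.65), H2-DMb2 (2.58), Anxa3 (2.53) and the ATP receptor gene P2rx7 (2.43), log2 values of the authors' deposited table. Mpo had 692 reads over the fresh-medium libraries and 0 over the supernatant libraries, which is at least 259-fold lower against a floor of 3 reads over the group. Other large falls were Mcpt8 (-5.68), the chemokine gene Cxcl9 (-4.71), the mast cell protease gene Prss34 (-4.08), the cathepsin gene Ctsg (-4.05), Thbs1 (-3.53), Ccl6 (-3.37), Csf2rb (-3.34), Ifitm1 (-3.33) and Csf2rb2 (-3.29) in the authors' deposited table. Csf2rb and Csf2rb2 are close paralogs between which reads can be split.

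Markers of liver and hepatoma cells were higher in 10 of 15 cases and lower in 0 (exact test, adjusted p = 6.01e-05). Without fresh-medium library 1, supernatant library 2 or supernatant library 3 there were 6 (exact test, adjusted p = 0.00976, 0.0230 and 0.0161), and 1 among genes with at least 10 CPM in the higher group (adjusted p = 1). Alb rose from 7 to 524 reads over 3 libraries each, 0.0733 ± 0.102 to 4.68 ± 1.57 FPKM (SD, n = 3 each). Ahsg had 1 and 74 reads, a ratio of 66.0 after scaling by library totals (95% exact interval 11.5 to 2642), and Apoa1 had 1 and 33 reads, a ratio of 29.4 (4.93 to 1197). Ttr had 0 and 24 reads, at least 7.14-fold higher. Monocyte, macrophage and neutrophil markers were lower in 7 of 18 cases and higher in 0 (exact test, adjusted p = 0.217). S100a8 had 126 reads in fresh medium and 1 in supernatant, a ratio of 141 (24.9 to 5623), S100a9 had 118 and 1, a ratio of 132 (23.3 to 5269), and Lyz2 fell by 3.83 in the authors' deposited table, with an adjusted p of 0.116 by edgeR on the listed genes. B cell markers were higher in 4 of 14 cases, among them Ms4a1 (2.23), Cd22 (1.77) and Cd74 (1.22) in the authors' deposited table, and lower in 0 (exact test, adjusted p = 0.0296). Natural killer cell genes Klra8 and Klra4 rose by 2.46 and 1.91, 2 of 9 listed (exact test, adjusted p = 0.181), the dendritic cell list had Batf3 higher and Flt3 at -1.20 (adjusted p = 0.0715 by edgeR on the listed genes), and the platelet gene Pf4 was at -1.96 as the 1 listed of 11 erythroid and platelet genes, all in the authors' deposited table. These intervals and floors cover counting error only.

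Genes listed lower were mostly of low counts. Their median mean normalised count was 7.81, against 81.0 for genes listed higher, and noncoding genes (lincRNA, antisense, intronic and unconfirmed transcripts) made up 27.2% of the lower and 2.90% of the higher genes. Processed pseudogenes went the other way, with 6.17% of the lower and 21.7% of the higher genes. Rn18s-rs5, mt-Rnr1 and mt-Rnr2, ribosomal RNA genes chosen from the genes listed lower after their values were seen, together took 0.860% to 1.09% of reads in fresh medium and 0.365% to 0.524% in supernatant. Among genes with at least 10 CPM in the higher group, 525 were listed, 353 higher and 172 lower, and 1 of the 7 lists with an adjusted p under 0.05 kept it by the exact test, the cell cycle list (adjusted p = 7.02e-07), while that of the ATF4 list became 0.0563. Without supernatant library 2, the activation, inhibitory receptor, glycolysis and B cell lists had an adjusted p of 0.0531 (exact test), which left 3 lists of 7, and without fresh-medium library 2 glycolysis had 0.197. By edgeR on the listed genes Egr1 had an adjusted p of 0.0542 without supernatant library 2, Eda2r and Me1 of 0.0733 and 0.139 without fresh-medium library 1, and Rn18s-rs5 of 0.120 with all libraries.

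**Figure D1:**
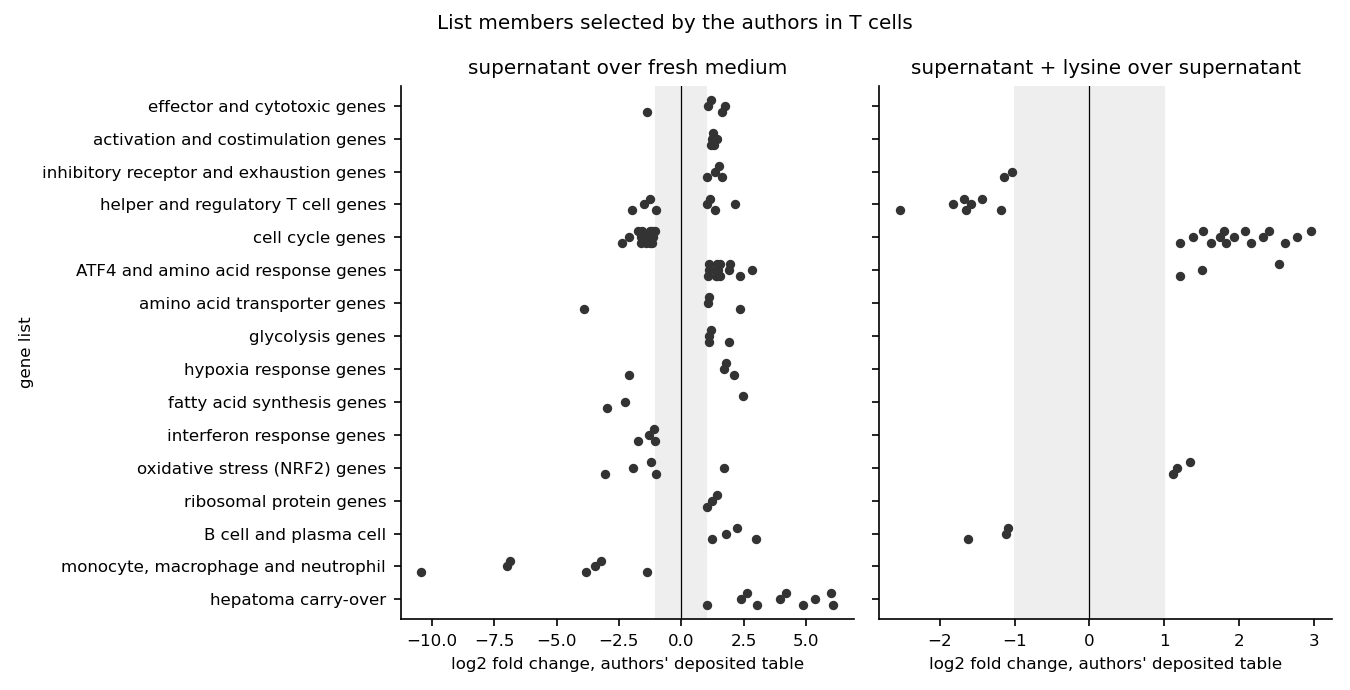
Each point is a gene of the list on the vertical axis that the authors selected, placed at its log2 fold change in the authors' deposited table, for supernatant over fresh medium (left) and for supernatant with lysine over supernatant (right). The grey band, from -1 to 1, holds no points because the tables list no such genes. The 15 cell cycle genes lie below 0 on the left and 15 lie above 0 on the right.

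The second comparison asked what lysine changed when it was added to the supernatant. Some genes of mitosis were higher with lysine, and genes of helper and regulatory T cells were lower. In the authors' deposited table, 15 of 28 cell cycle genes were listed higher and 0 lower, and 7 of 18 helper and regulatory T cell genes were listed lower and 0 higher. The authors' deposited table listed 372 genes, 270 higher and 102 lower with lysine. By edgeR on the listed genes, 61 were lower without supernatant library 1, and 62, 58 and 60 without library 1, 2 or 3 with lysine. A pathway table beside it, also the authors' deposited table, gave the cell cycle pathway 15 higher and 0 lower genes (q = 5.98e-08) and cytokine receptor interaction 5 higher and 15 lower (q = 1.55e-10).

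Cenpf rose by 2.97 ± 0.10, Ccnb2 by 2.77 ± 0.14, Ccnb1 by 2.62 ± 0.10 and Plk1 by 2.40 ± 0.24 (log2, SE) in the authors' deposited table, and Mki67 rose by 2.32 ± 0.07. Mki67 went from 12.2 ± 0.740 FPKM in supernatant to 61.6 ± 3.59 FPKM with lysine, and Cenpf from 0.520 ± 0.0624 to 4.10 ± 0.303 FPKM (SD, n = 3 each). The largest rises outside that list included the ubiquitin-conjugating enzyme gene Ube2c (3.17), the spindle genes Hmmr (2.92) and Aspm (2.52), Prr11 (2.77), the kinesin gene Kif2c (2.44), Fam171b (3.35) and Avil (2.45) in the authors' deposited table. The direction of the cell cycle list differed from that of the other listed genes at an adjusted p of 0.0471 by Fisher's exact test (7 lists with a listed member). It had 15 members higher at every setting, but its adjusted p lay between 0.0519 and 0.0605 without 1 of 5 libraries in turn (supernatant 1 and 3 and each of supernatant with lysine), at 0.0603 for 2-fold changes alone with a pseudocount of 5, and at 0.175 among genes of at least 10 CPM, where 115 of 138 listed genes were higher.

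The helper and regulatory T cell genes that fell were Il9 (-2.54), the chemokine receptor gene Ccr8 (-1.83), Il17f (-1.68), Il5 (-1.66), Il22 (-1.59), Il17a (-1.43) and Foxp3 (-1.18), the regulatory T cell factor gene, in the authors' deposited table (exact test, adjusted p = 6.99e-04). Foxp3 was at 10.6 ± 0.470 FPKM in supernatant and 4.70 ± 0.344 FPKM with lysine, and Il22 at 24.6 ± 0.895 and 8.19 ± 0.603 FPKM (SD, n = 3 each). Il9 rested on 42 and 7 reads, and its adjusted p was 0.373 without supernatant library 2 (edgeR on the listed genes), and that of Il17f 0.300 without library 3 with lysine. Cd200 and Lag3, of the inhibitory receptor and exhaustion list, fell by 1.14 and 1.03 in the authors' deposited table (2 of 16 lower, exact test, adjusted p = 0.131). Id3 at -1.04 was the 1 listed of 16 naive and memory genes there (exact test, adjusted p = 0.384). The B cell and antigen presentation genes Jchain (-1.63), H2-Aa (-1.11) and Cd74 (-1.09) were lower in the authors' deposited table, 3 of 14 (exact test, adjusted p = 0.0471), and 0.233 among genes of at least 10 CPM, where 1 was left. The other genes of largest fall were the enkephalin gene Penk (-2.40), Stra6 (-1.74), the chemokine gene Ccl22 (-1.60), the cytokine gene Lif (-1.42), Lad1 (-1.35), the ribosome assembly gene Rrp9 (-1.23) and Zbtb32 (-1.15) in the authors' deposited table.

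Of the ATF4 list 3 genes were listed with lysine, all higher, Vldlr (2.53), Nupr1 (1.51) and Stc2 (1.21) in the authors' deposited table (exact test, adjusted p = 0.565). NRF2 genes were also higher in 3 of 16 cases, Osgin1 (1.35), Nqo1 (1.17) and Hmox1 (1.11) in the authors' deposited table (exact test, adjusted p = 0.565). No member was listed of the effector, activation, IL-2 and STAT, aminoacyl-tRNA synthetase, amino acid transporter, lysine metabolism, glycolysis, hypoxia, oxidative phosphorylation, cholesterol, fatty acid, interferon, p53, unfolded protein, ribosomal protein, T cell identity, myeloid, dendritic, natural killer, erythroid and hepatoma lists. Slc3a2, Stat3, Ifng, Gzmb, Prf1, Pdcd1, Asns, Trib3, Slc7a5 and Slc7a1 were not listed either.

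Of 177 genes listed in both tables, 118 were lower in supernatant and higher with lysine, 32 were higher and then lower, 15 higher in both and 12 lower in both in the authors' deposited table. Independent lists drawn from the 24046 genes tested in the first comparison would share 21.3, 3.36, 8.90 and 8.04 genes in these directions. With the 16638 genes tested in the second, these numbers would be higher, and nearer to the 15 and 12 genes of equal direction. Both comparisons used the same supernatant libraries. In 50 simulations of 2884 unchanged genes with shared supernatant libraries 0 genes were called in either comparison, so these give no overlap of calls. Among the 177 simulated genes with the largest changes in both comparisons 94.7% on average went in opposite directions, against 84.7% observed. Shared libraries can thus give opposite directions without an effect. Since no simulated gene was called, that share is no baseline for the listed genes. It cannot decide whether the opposite directions came from lysine. With 1 supernatant library for one comparison and the other 2 for the other, 131 to 133 of the 177 genes moved 2-fold in opposite directions, without a test, as 3 libraries do not make 2 sets of at least 2. These genes had been selected with all 3 libraries, so part of the excess may come from the shared libraries.

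The level with lysine was set beside fresh medium for these 177 genes, with edgeR and library totals. Adjusted p was taken over these selected genes alone, so fewer would pass with an adjustment over all genes tested. With lysine, 97 genes differed from fresh medium, 71 higher and 26 lower (edgeR, adjusted p under 0.05), of which 37 also had an absolute log2 fold change of at least 1, 20 higher and 17 lower. Among the 118 genes that were lower in supernatant and higher with lysine, 48 ended above fresh medium, 12 below, and 58 did not pass the test, while among the 32 with the opposite course 8 ended above, 2 below and 22 did not pass. The 15 genes that were higher in both comparisons lay above fresh medium, among them Aldh1l2 (3.96 ± 0.13, log2, SE, adjusted p = 8.67e-30) and Avil (4.30 ± 0.13, adjusted p = 6.16e-31, edgeR), and the 12 that were lower in both lay below it, as follows from their selection. Of 14 cell cycle genes in both tables, 12 were above fresh medium with lysine and 0 below. Ccna2 was left out, for 11, with only the 2 groups compared (adjusted p = 0.0547), with the library numbers as a block (0.0593), and without fresh-medium library 1 (0.156) or library 2 (0.0543) or 3 (0.126) with lysine. Ccnb1 was at 19.9 CPM in fresh medium, 7.27 in supernatant and 45.1 with lysine, a log2 ratio of lysine to fresh medium of 1.18 ± 0.10 (SE, edgeR, adjusted p = 7.08e-14). Mki67 was at 306, 123 and 620 CPM, a log2 ratio of 1.02 ± 0.19 (edgeR, adjusted p = 0.00275), whereas Rrm2, the ribonucleotide reductase gene, had -0.09 ± 0.07 and Cdk1 0.17 ± 0.10 (edgeR, adjusted p = 0.260 and 0.136). Stra6 stayed above fresh medium at 9.05 against 0.285 CPM (edgeR, adjusted p = 1.72e-22). Lif, Cd200 and Lag3 stayed above it by 0.74, 0.45 and 0.29, and Il22 lay at -0.49 (log2, edgeR, adjusted p = 2.96e-12, 7.83e-07, 0.00241 and 0.00118).

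**Figure D2:**
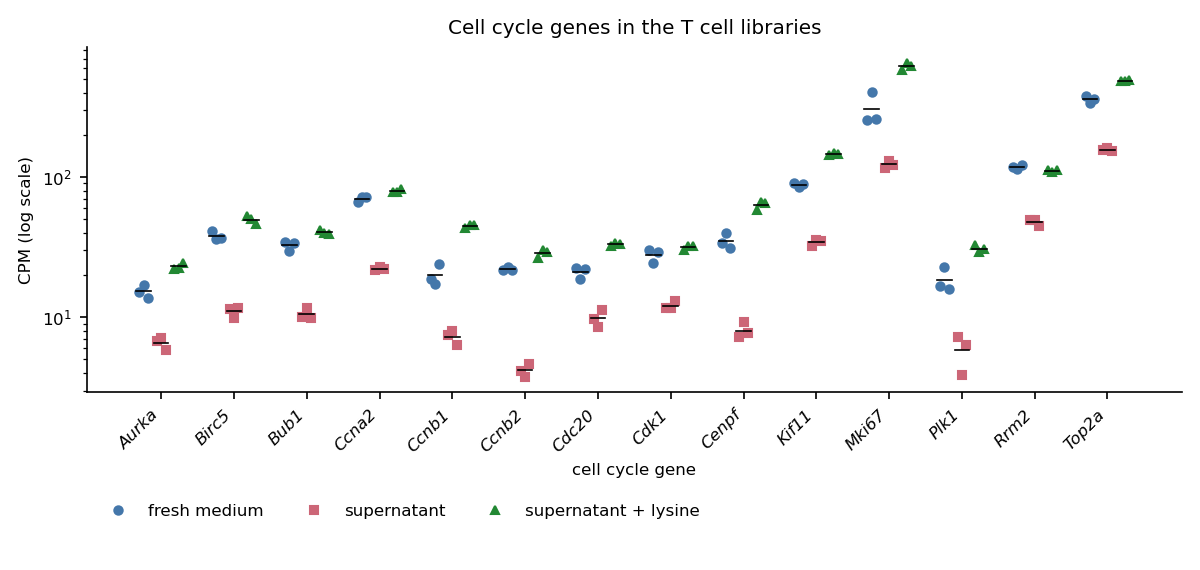
CPM on a log axis of the 14 cell cycle genes listed in both T cell tables, with 1 point per library in fresh medium, supernatant and supernatant with lysine and a line at the mean of each 3. In each gene the supernatant libraries lie below the other 2 groups, and for Mki67 the means are 306, 123 and 620 CPM.

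The last comparison asked what the SLC3A2 knockdown virus changed in Huh-7 cells. SLC3A2 (ENSG00000168003, chromosome 11, 62856102 to 62888875 in the deposited table, genome build not given in the sources used here) had 3899, 3370 and 3946 counts with the control virus and 1326, 1229 and 1550 with the knockdown virus. It fell from 171 ± 5.10 to 61.2 ± 5.68 CPM (SD, n = 3 each), a log2 fold change of -1.49 ± 0.06 (SE, edgeR, adjusted p = 7.12e-16). SLC7A5, its partner in leucine transport, fell further, from 257 ± 13.7 to 48.7 ± 1.08 CPM (SD, n = 3 each, log2 fold change -2.40 ± 0.05, edgeR, adjusted p = 1.32e-19). With 1 knockdown sample, effects of SLC3A2 loss cannot be told apart from other effects of the knockdown virus. Genes of amino acid transport, glycolysis, lipid synthesis and ribosomal proteins were mostly lower in the knockdown cells, and those of interferon response and antigen presentation mostly higher, but none of these lists passed camera's test with an estimated correlation (adjusted p = 0.398 each).

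Of 16870 genes tested, 8917 changed, 4527 higher and 4390 lower (edgeR, adjusted p under 0.05), and 1416 of them by an absolute log2 fold change of at least 1, 926 higher and 490 lower. Among genes of at least 10 CPM the latter were 499, 272 higher and 227 lower. The balance of directions was not stable: with DESeq2 3522 were higher and 4073 lower, and the authors' deposited table had 3534 and 4088. It also turned without control library 2 (4054 higher, 4067 lower) or 3 (4055, 4066) and without knockdown library 1 (4314, 4343) or 3 (4414, 4433). With library totals as the only scaling 5810 were higher and 3335 lower of 9145, and the median log2 fold change of all genes was 0.12 against 0.02. Log2 fold changes below are on TMM scaling unless another scaling is named, and no median was subtracted from them.

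Of 23 amino acid transporter genes 14 fell and 3 rose. Beside SLC7A5 these were SLC6A14 (-1.47 ± 0.07), SLC6A9 (-1.33 ± 0.07) and SLC43A2 (-1.08 ± 0.08), all log2 fold changes with SE, and SLC7A11, the cystine transporter gene, fell by 0.92 ± 0.07 (edgeR, adjusted p = 3.47e-11). The list was lower than other genes by camera with a preset correlation (adjusted p = 0.00317) but not with an estimated one (adjusted p = 0.398 with an estimated correlation), and its median log2 fold change was -0.49. Among 10000 random lists matched on expression and length the medians of the lists that passed camera lay at percentile 0 for amino acid transporters, 0.15 for glycolysis, 1.5 for ribosomal proteins, 5.66 for cholesterol, 12.0 for fatty acids, 15.45 for aminoacyl-tRNA synthetases, 99.96 for antigen presentation and 99.99 for interferon response. The basigin gene BSG, another partner of membrane transporters, fell by 2.23 ± 0.05 from 773 ± 16.4 to 165 ± 10.3 CPM (SD, n = 3 each). Of 32 ATF4 and amino acid response genes 16 fell and 7 rose (camera adjusted p = 0.0510, and 0.617 with an estimated correlation), with SLC7A5 and the stress cytokine gene GDF15 (-1.66) lower and NUPR1 (1.37) and DDIT3 (1.04) higher. TRIB3 fell by 0.98 ± 0.05 (edgeR, adjusted p = 9.62e-14), and ASNS, at 3.14 ± 0.554 and 3.83 ± 0.368 CPM (SD, n = 3 each), had a log2 fold change of 0.28 ± 0.17 (edgeR, adjusted p = 0.178). Of 20 aminoacyl-tRNA synthetase genes 15 fell and 1 rose, led by YARS (-0.71), VARS (-0.54), IARS (-0.54) and RARS (-0.37), with camera adjusted p = 0.00355 (adjusted p = 0.398 with an estimated correlation). With library totals alone 8 of these fell and 2 rose. Lysine metabolism genes rose in 10 of 17 cases and fell in 4 (camera adjusted p = 0.205, and 0.398 with an estimated correlation): CRYM (0.89), HYKK (0.88) and PIPOX (0.83), of lysine breakdown, rose, and PLOD1, which hydroxylates lysine in collagen, fell by 1.27.

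Ribosomal protein genes fell in 24 of 26 cases and rose in 0, with a median log2 fold change of -0.26 (camera adjusted p = 2.53e-06, and adjusted p = 0.398 with an estimated correlation). With library totals alone 19 fell and 0 rose. RPL11, RPL7 and RPS3 fell by 0.52, 0.42 and 0.40. Glycolysis genes fell in 16 of 19 cases and rose in 2 (camera adjusted p = 5.50e-04, and adjusted p = 0.398 with an estimated correlation), with HK2 at -0.86, the phosphofructokinase gene PFKL at -0.82, the glucose transporter gene SLC2A1 at -0.67 and ENO2 at 0.61. Fatty acid synthesis genes fell in 8 of 11 cases and rose in 1 (camera adjusted p = 0.0227, and adjusted p = 0.398 with an estimated correlation): ME1 fell by 1.05, the desaturase gene SCD by 0.96 and the citrate lyase gene ACLY by 0.94, and the elongase gene ELOVL6 rose by 0.98. Cholesterol genes fell in 14 of 23 cases and rose in 6 (camera adjusted p = 0.0367, and adjusted p = 0.398 with an estimated correlation), with FDPS at -0.62 and TM7SF2 at 1.05.

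Interferon response genes rose in 14 of 20 cases and fell in 1 (camera adjusted p = 0.00484, and adjusted p = 0.398 with an estimated correlation). The RNA sensor gene IFIH1 rose by 1.84, MX1 by 1.70, BST2 by 1.36 and CXCL10 by 1.01, from low levels: MX1 was at 1.33 ± 0.190 and 4.35 ± 0.455 CPM (SD, n = 3 each), and BST2 did not pass with DESeq2 (adjusted p = 0.145; 0.0577 to 0.145 over the alternatives that ended its call). Antigen presentation genes rose in 10 of 14 cases and fell in 2 (camera adjusted p = 0.0227, and adjusted p = 0.398 with an estimated correlation), with the peptide transporter gene TAP1 at 2.28, HLA-B at 2.23 and the immunoproteasome genes PSMB8 and PSMB9 at 2.15 and 1.75. TAP1 was at 1.32 ± 0.569 and 6.48 ± 0.490 CPM (SD, n = 3 each). Hepatocyte genes rose in 12 of 23 cases and fell in 6 (camera adjusted p = 0.0510, and 0.464 with an estimated correlation), led by the urea cycle gene CPS1 (2.14), the fibrinogen gene FGG (1.00), TTR (0.76) and GPC3 (0.74).

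The remaining lists did not pass camera's test. Cell cycle genes fell in 13 and rose in 9 of 28 cases (camera adjusted p = 0.192): TOP2A fell by 1.59, BIRC5 by 1.26, MCM7 by 1.06 and MCM2 by 0.91. In the unfolded protein response list 8 of 16 rose and 5 fell (0.503), with the chaperone gene HSPA5 at -1.19, DNAJB9 at 0.91, HERPUD1 at 0.77 and CRELD2 at 0.70. NRF2 and ferroptosis genes fell in 7 and rose in 5 of 19 cases (0.584), with NQO1 at -1.02, SRXN1 at 0.81 and TFRC at 0.57. In the checkpoint ligand and chemokine list 4 of 10 rose and 2 fell (0.503), with CXCL5 at -2.06, CXCL1 at 0.70, CXCL2 at 0.62 and CD47 at 0.47, and 5 rose when adjusted over the list alone, which left all other counts of members as they were. Epithelial and integrin genes rose in 9 and fell in 6 of 19 cases (0.503), with ITGA3 at 2.28, ZEB2 at 1.52, CDH1 at 1.40 and CD44 at 0.77. CD44 did not pass with DESeq2 (adjusted p = 0.0889), nor CXCL1 and SRXN1 without control library 3 (edgeR, adjusted p = 0.0874 and 0.0535). Oxidative phosphorylation genes fell in 10 and rose in 5 of 30 cases (0.333), with CYCS at -0.65, COX5A at 0.63, NDUFA9 at -0.54 and SDHD at -0.36. Of 15 hypoxia genes 4 rose and 2 fell (0.867), with ADM at 1.00, PFKFB4 at -0.72, MXI1 at 0.55 and P4HA1 at -0.52, and of 14 p53 genes 5 rose and 5 fell (0.874), with SESN1 at 1.09, BCL2L11 at 0.89, MDM2 at -0.86 and TP53INP1 at 0.80. The values in parentheses are camera adjusted p, and none was below 0.505 with an estimated correlation. Of the leukocyte markers 2 of 10 were measured and LYZ fell by 1.35 (0.333), and of the fibroblast and endothelial markers 4 of 7 rose and 1 fell (0.434), COL1A1 by 2.32 from 0.230 ± 0.0445 to 1.16 ± 0.503 CPM (SD, n = 3 each), with LUM at 1.39 and PDGFRA at 1.28 higher and PDGFRB at -1.28 lower. With library totals alone the cell cycle list had 12 higher and 12 lower, oxidative phosphorylation 8 and 8, and NRF2 9 and 6. Median and test differed in sign for the epithelial list (median -0.00, mean 0.30, higher by camera) and the NRF2 list (median 0.03, mean -0.06, lower by camera).

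The largest rises in the knockdown cells were ADH1B, an alcohol dehydrogenase gene, at 4.94 ± 0.24 (0.346 ± 0.254 to 10.6 ± 0.742 CPM, SD, n = 3 each), the glucose transporter gene SLC2A2 at 3.75, RFX6 at 3.71, FAM198B (11.3-fold), the prostaglandin receptor gene PTGER4 at 2.86, the metallothionein gene MT1F at 2.85, SPTSSB at 2.63, the sucrase gene SI at 2.60, the glutamate receptor gene GRM3 at 2.54 and the retinoic acid receptor gene RARB at 2.52. Among the largest falls were NPTX2 at -2.44, SLC7A5, ERLIN1 at -2.35, ANGPTL8 at -2.31, LRP12 at -2.25, BSG, EI24 at -2.18, AL365181.3 at -2.17 and PLBD2 at -2.08, all log2 fold changes by edgeR. AL365181.3 is an antisense gene, and without strand its reads cannot be told apart from those of its partner.

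**Figure D3:**
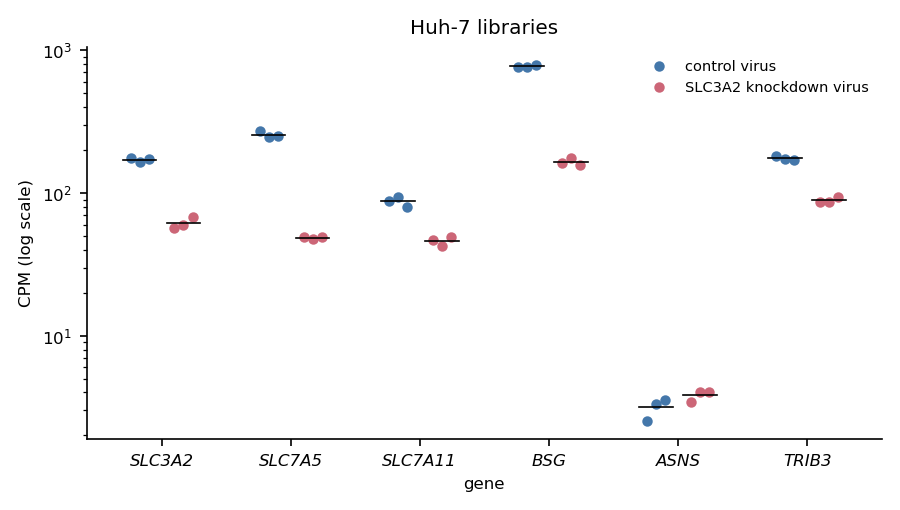
CPM on a log axis of 6 genes in each Huh-7 library, with 3 points and a line at their mean for the control virus and for the SLC3A2 knockdown virus. SLC3A2 lies at 171 and 61.2 CPM on average and SLC7A5 at 257 and 48.7 CPM, while the ASNS libraries overlap.

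**Figure D4:**
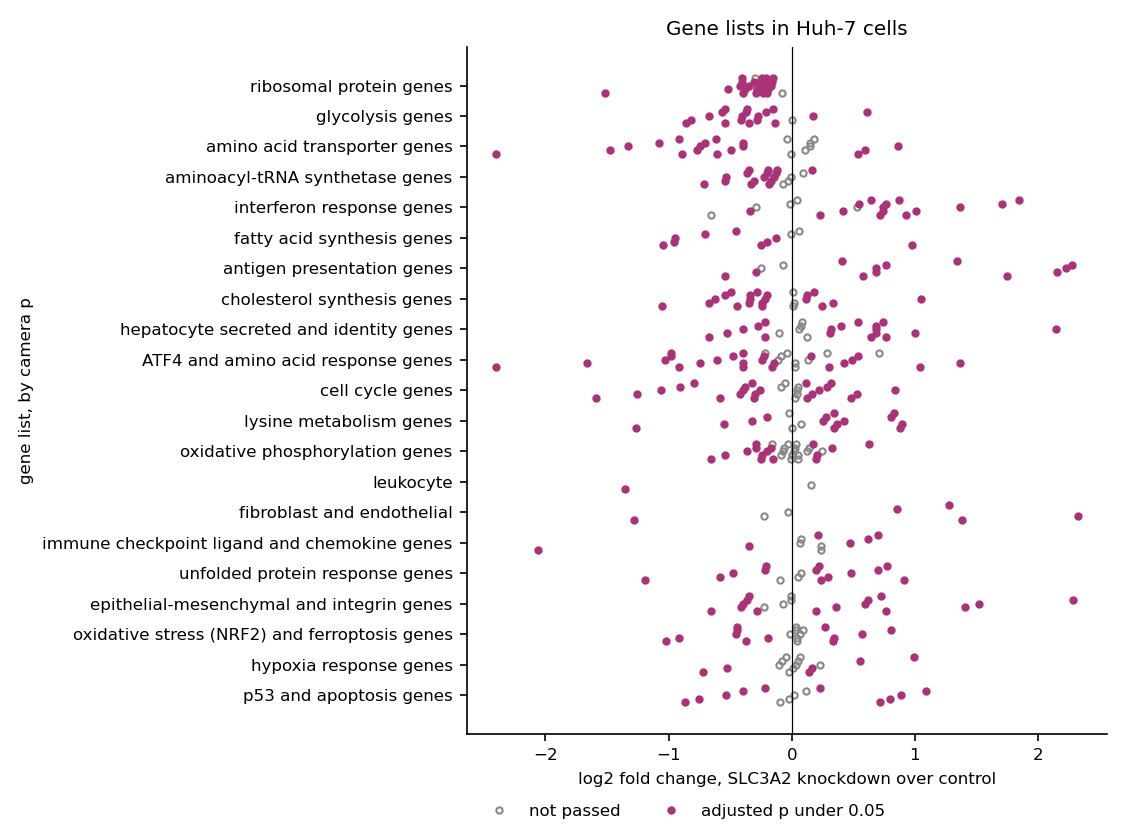
Each point is a gene of the list on the vertical axis at its log2 fold change, knockdown over control, in Huh-7 cells. Filled points passed edgeR at an adjusted p under 0.05 and open points did not. In the ribosomal protein list 24 filled points lie below 0, and in the interferon list 14 lie above 0.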

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

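Chosen after the data were seen were edgeR on the listed genes, the count of listed genes without overlap, the pseudocount of 1, different supernatant libraries for the 2 T cell comparisons, the directions of the largest simulated changes, and, in Huh-7, library totals alone and the removal of mitochondrial genes. No named gene and no list past the threshold turned its direction. The balance of Huh-7 calls turned with DESeq2 (3522 higher, 4073 lower), median-ratio factors (4401, 4521) and no filter (4259, 4577) and without 1 of 4 libraries. With median-ratio factors the median of the p53 list went from 0.00 to -0.01, and with library totals the medians of the cell cycle (-0.07 to 0.03), oxidative phosphorylation (-0.02 to 0.08) and epithelial (-0.00 to 0.09) lists turned, as did the NRF2 members (5 higher and 7 lower to 9 and 6). With an absolute log2 fold change of at least 1 the calls in Huh-7 were 1416 (499 at 10 CPM or more) and those of lysine against fresh medium 37. At least 10 CPM left 525 and 138 listed genes and 1 list in each T cell table (1 of 7 and 1 of 3), with fewer genes to test. Other total counts stayed within 1.5 times: 6648 to 9147 in Huh-7 (without 1 library 8102 to 8847), 1815 to 2683 and 259 to 371 for the tables, 90 to 104 for lysine against fresh medium without 1 library, and 113 to 133 against 150 for opposite directions. Lower genes alone fell more, from 1896 to 1174 without T_SUP replicate 2 and from 102 to between 58 and 62 without T_SUP replicate 1 or any T_SUP_LYS replicate. Lists of the first table numbered 3 to 7 without 1 library and 3 without T_SUP replicate 2, and those of the second 2 to 3. The cause was not tested.

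With an estimated correlation camera's adjusted p was 0.398 for the aminoacyl-tRNA synthetase, amino acid transporter, glycolysis, cholesterol, fatty acid, interferon, antigen presentation and ribosomal lists. By fry it was 0.00136 for ATF4, 0.00454 for lysine metabolism, 4.28e-04 for cell cycle and hepatocyte, 0.00194 for NRF2, 0.0141 for p53, 0.00755 for epithelial, 0.00156 for leukocyte and 0.0106 for fibroblast genes, since fry does not compare with other genes. With median-ratio size factors it was 0.0496 for the ATF4 and hepatocyte lists. Of 5549 values of 400 Huh-7 genes 5291 kept their side of the threshold, 71 moved past it and 187 fell short (53 genes); of 1584 values of 176 T cell results 1519 kept it and 65 fell short (16 results).

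Library numbers paired weakly at most: residual correlations of equal numbers ran from -0.0720 to 0.0688, from -0.0204 to 0.127 and, in Huh-7 cells, from 0.0122 to 0.0617. Unequal numbers in Huh-7 cells gave -0.0670 to 0.0118, below those of equal numbers, so a weak pairing there is not excluded. As a block the library numbers gave 2367, 291, 97 and 9147 calls and 7 and 3 lists. Since the T cell tables hold selected genes, DESeq2, no filter, median-ratio factors, an adjusted p of 0.1, the 2 groups alone, and camera and fry were not run on them; nor were DESeq2, median-ratio factors, no filter, pseudocounts and an authors' table for lysine against fresh medium. Genes of a few reads limit what depth allows, and the lower listed genes had a median mean of 7.81.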

Other observations

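The tests of the cell cycle pattern, of the low-count genes, of the share of T cells and of the splits for lysine against fresh medium were chosen after the results were seen, and those of liver-type RNA and of the Huh-7 splits before.

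Mitochondrial genes took 7.01%, 6.84% and 6.30% of Huh-7 counts with the control virus and 6.01%, 5.55% and 5.03% with the knockdown virus. In each of 2 comparisons 1 of 10 splits of the libraries, the real one, gave as many calls (8917 in Huh-7 and 98 for lysine against fresh medium, and at most 0 in the others), and 10 splits are too few for a share under 0.05.

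Cell cycle genes were lower in supernatant and higher with lysine. Of the genes past the adjusted threshold at any fold change 24.1% were listed lower in supernatant and 5.85% higher with lysine. These shares cannot decide whether scaling of the libraries made the pattern, since the authors' size factors had already scaled the fold changes. On library totals alone, the 14 cell cycle genes of both tables were still 2-fold lower in supernatant and 2-fold higher with lysine. Their median log2 ratios were -1.41 and 2.02, so the pattern did not hang on the choice between these 2 scalings. Noise between the shared supernatant libraries was argued against for these 14 genes only. Their highest p in either comparison, from the authors' deposited tables, was 0.0184 after multiplication by the number of genes tested. That is a stricter bound than the one they were listed by, but the same p-values had selected them. The 2 comparisons share the supernatant libraries and are not independent, and p measures only the spread between libraries. A difference between single cultures stays open, since each group came from 1 GEO sample, as does an effect of lysine on proliferation, which the design names and which was not tested.

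Many low-count genes were lower in supernatant. One scaling error between the groups was argued against, since 82.9% of listed genes with a mean under 50 but 36.9% of those above were lower. More reads from RNA or DNA outside mature messenger RNA in the fresh-medium libraries may explain part of it: noncoding classes were more frequent among lower genes also under a mean of 50 (odds ratio 6.63). No biological explanation was tested.

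Transcripts of other cell types differed between T cell libraries. B cell markers were listed higher and myeloid markers lower in supernatant (Fisher's exact p = 0.00303), so markers of other cell types did not all rise. This does not decide whether the share of T cells was smaller, since other cell types can change in different directions. The test also counts markers of the same cell type as independent. Liver-type RNA in the supernatant libraries remains (Fisher's exact p = 4.81e-06 before adjustment), with 10 of 15 hepatoma list members higher, of which 1, Trf, had 10 or more reads in fresh medium. Whether it came with the Hepa1-6 supernatant or from another liver source stays open. The other 5 members, Afp (alpha-fetoprotein), Apoe, Serpina1a, Krt8 and Hnf4a, were not listed. A change of the myeloid or B cells themselves could add to the pattern and was not tested.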
